A study of Mus musculus with 18 samples.

How the data were processed

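Bulk RNA sequencing was done on micropunches of medial prefrontal cortex (mPFC) and amygdala from male mouse offspring of dams given a single injection of poly(I:C), a synthetic double-stranded RNA, or saline vehicle on gestational day 12. Per the labels, each library carries a tissue and a phenotype (control, resilient or susceptible). The labels do not say which injection the dam of each animal received. There are 6 groups of 3 libraries. Replicates are separate offspring per the design text (n = 3 per phenotype), and the replicate numbers differ between tissues. Whether both tissues come from the same animals, and which animals share a litter, is not given in the sources used here.

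The deposited files hold raw read counts per Ensembl gene, 1 file per library, with 25700 genes. Per the submitters' processing notes the tools were bcl2fastq 2.19, Trimmomatic, STAR 2.7.1, featureCounts and edgeR with the genome build GRCm38.p5. Settings, strand setting, annotation release and filters are not given in the sources used here. Gene symbols, coordinates, biotypes, GC content and exon overlaps were taken from GENCODE mouse release 21 (GRCm38): 25587 identifiers have a symbol, 113 have none, and 4264 genes have exons that overlap another gene. As the strand setting is not stated, reads of such genes are uncertain. No count was found in any library for 5228 genes.

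Library totals ran from 5587054 counts (amygdala susceptible 32) to 14257549 (mPFC control 4). Totals were at least 12841961 in mPFC controls, 11162820 in mPFC resilient, 7639338 in mPFC susceptible, 11500815 in amygdala controls and 11322730 in amygdala resilient libraries. Genes detected per library numbered 16509 to 17943. Within groups, libraries correlated at 0.978 to 0.991 (Spearman), and no library duplicated another.

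Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 (figures with matplotlib 3.10.9). Each tissue was fitted on its 9 libraries (6 residual degrees of freedom) with filterByExpr by phenotype, TMM scaling, glmQLFit with robust estimation and glmQLFTest. This tested 14272 genes in mPFC (biological coefficient of variation 0.138, scaling factors 0.967 to 1.07) and 14585 in amygdala (0.103, 0.982 to 1.01). A fit of all 18 libraries (12 residual degrees of freedom) tested 14828 genes (0.122, 0.963 to 1.04). It served the comparison of tissues in controls and the tissue differences, defined as the amygdala effect minus the mPFC effect. Within each tissue the contrasts were susceptible against control, resilient against control, susceptible against resilient, and both phenotypes together against control. P values were adjusted by Benjamini-Hochberg over all genes tested and called under 0.05. CPM use the effective library sizes of the fit.

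The comparisons, the 36 gene lists (cell types and regions, neuronal activity, immune signalling, transmitter systems, stress, energy metabolism, translation, disease risk and development) and the rule for named genes were fixed before the data were examined. Lists with at least 5 genes tested were compared with camera on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over the lists. They were also tested with the correlation estimated from the data, and with fry, for members that move together or in either direction. Counts adjusted over the list alone use the members' own p values. The named genes of a comparison are the 10 largest rises and the 10 largest falls among genes that pass, have a mean CPM of at least 1 and do not overlap between groups. Where fewer than 10 genes pass, the 5 smallest p per direction are given as values that did not pass. For each list that passed, members come from the 4 with the smallest p. For every cell type list the median is given. For the tissues in controls the rule takes 5 genes per direction and the passing members of 6 lists, and for the tissue differences the 5 smallest p.

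The pipeline was tested on simulated data with 200 changed genes in 3 runs. In the mPFC susceptible-control design it recovered 38.3, 74.9 and 91.8 percent of genes changed 1.5, 2 and 4-fold, with 4.92 percent false calls. The amygdala design recovered 48.7, 79.5 and 96.4 percent, with 6.78 percent false calls, the pooled mPFC design 47.7, 81.3 and 95.9 percent, with 6.95 percent, and the tissue difference of susceptible against control 19.3, 66 and 84.8 percent, with 5.32 percent. Lists of 20 genes shifted by 0.5 were found in 3 of 3 runs. The simulated genes were drawn independently, with no GC content trend and no library set apart. These rates therefore do not cover genes that move together or such trends in the real libraries.

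The settings also run were DESeq2 1.42.0 with its own size factors, RLE scaling, no low-count filter, a fit of only the 2 groups compared, a fit of all 18 libraries, 1 surrogate variable from sva 3.50.0, an estimated correlation for the lists, and leaving out each library in turn. Where a left-out library leaves few replicates, the remaining ones are assumed to vary like the other groups. Settings added after the data were seen remove each library's lowess trend (span 0.3) of log2 CPM against transcript GC (known for 99.8 percent of genes), alone or with that against exonic length, or set aside libraries in doubt. These are mPFC control 4, amygdala resilient 27 and amygdala susceptible 32, which stand apart in principal components of the 1000 most variable genes. The lists under other settings were run for the 6 comparisons of phenotypes taken singly. Behavioural scores are not used here.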

Results

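Medial prefrontal cortex (mPFC) and amygdala were compared among control, resilient and susceptible male offspring, with 3 libraries per phenotype and tissue. Group values are mean CPM (counts scaled to library size) ± SD, and changes are log2 fold changes ± standard error with the edgeR adjusted p. The genes named as the largest rises and falls have library values that do not overlap between the groups.

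Genes of myelinating oligodendrocytes were lower in the mPFC of susceptible offspring than of controls (n = 3 per group). Mag, a myelin adhesion glycoprotein, fell from 114 ± 17.9 to 46.9 ± 2.51 CPM (-1.28 ± 0.13, adjusted p = 0.00649). Mbp, myelin basic protein, fell from 1717 ± 366 to 756 ± 51.8 CPM (-1.18 ± 0.16, adjusted p = 0.0112). Hapln2, a link protein of the node of Ranvier, and Myrf, the transcription factor that drives myelin genes, fell by 1.47 ± 0.19 and 1.03 ± 0.15 on the log2 scale. Of the 22 measured members, 16 fell and 0 rose (18 and 0 adjusted over the list alone). The list gave a median of -0.89, adjusted p = 2.47e-11, adjusted p = 0.638 with an estimated correlation.

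Of 12 oligodendrocyte precursor list genes 4 fell (5 over the list alone). They include Olig1 (-1.12 ± 0.13, adjusted p = 0.00649) and Sox10 (-1.26 ± 0.15, adjusted p = 0.00730), transcription factors of the lineage. The list gave a median of -0.41, adjusted p = 0.00191, adjusted p = 0.638 with an estimated correlation. It did not pass without the GC trend and control 4. Ribosomal protein genes fell in 13 of 36 cases (16 over the list alone), among them Rpl13 (-0.58 ± 0.12) and Rps21 (-0.78 ± 0.16), with a median of -0.21, adjusted p = 2.55e-05, adjusted p = 0.638 with an estimated correlation. Of the immediate early genes, which neuronal activity induces, 5 fell and 1 rose of 28 (6 and 2 over the list alone). They include Egr4 (-1.69 ± 0.19, adjusted p = 0.00649) and Junb (-1.81 ± 0.38, adjusted p = 0.0272), and the list gave a median of -0.49, adjusted p = 0.0153, adjusted p = 0.716 with an estimated correlation. Nuclear oxidative phosphorylation genes fell in 9 of 33 cases (11 lower and 1 higher over the list alone), with Ndufa2 at -0.77 ± 0.16 and Uqcrq at -1.06 ± 0.21 (median -0.10, adjusted p = 0.0266, adjusted p = 0.716 with an estimated correlation). Striatal medium spiny neuron genes fell in 2 of 15 cases over all genes and over the list alone, Adora2a, an adenosine receptor, by 1.38 ± 0.32 (median -0.49, adjusted p = 0.0266, adjusted p = 0.446 with an estimated correlation). Dopamine signalling genes fell in 4 of 18 cases (6 lower and 1 higher over the list alone), Ddc, which makes dopamine from L-DOPA, by 0.90 ± 0.25 (median -0.33, adjusted p = 0.0426, adjusted p = 0.617 with an estimated correlation). With a library left out, lists did not pass as follows (adjusted p in brackets): immediate early without control 5 (0.193, median -0.26) or susceptible 15 (0.233), striatal without control 5 (0.114) or susceptible 14 (0.0632), oxidative phosphorylation without control 5 (0.200) or susceptible 16 (0.0763), dopamine without control 4 (0.0651), control 5 (0.159) or susceptible 14 (0.0865).

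In the other direction, neurodevelopmental disorder risk genes rose in 9 of 42 cases (17 higher and 2 lower over the list alone), with a median of 0.20, adjusted p = 0.00191, adjusted p = 0.195 with an estimated correlation. Grin2b, an NMDA receptor subunit, rose from 689.9 ± 27.2 to 945 ± 77.3 CPM (0.45 ± 0.09, adjusted p = 0.0191), and Grin2a, another, rose by 0.53 ± 0.12. Mitochondrially encoded genes rose in 2 of 7 tested (15 listed), mt-Nd5 by 0.53 ± 0.12 and mt-Nd6 by 0.61 ± 0.16. Over the list alone 7 rose (median 0.31, adjusted p = 0.00191, adjusted p = 0.638 with an estimated correlation). Among named rises, Glra3, a glycine receptor subunit (ENSMUSG00000038257, chromosome 8, 55940460 to 56130070), went from 9.74 ± 1.73 to 18.5 ± 3.68 CPM (0.92 ± 0.18, adjusted p = 0.0191). Sh2d4b, an SH2 domain gene, rose by 1.66 ± 0.37, adjusted p = 0.0242. Ptgfr, the prostaglandin F receptor, rose by 1.61 ± 0.46, adjusted p = 0.0475. The others were the unclassified gene models Gm37899 (1.79 ± 0.38), Gm38299 (1.17 ± 0.33), Gm45457 (0.91 ± 0.25) and Gm37773 (0.87 ± 0.22), with Vmn2r84 (1.58 ± 0.41), 4930447C04Rik (1.08 ± 0.23) and Dnah7c (1.07 ± 0.31).

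Among named falls, Nxph4, a neurexophilin (ENSMUSG00000040258, chromosome 10, 127525473 to 127534559), went from 5.43 ± 3.05 to 0.609 ± 0.305 CPM (-3.06 ± 0.47, adjusted p = 0.0135). Prr7, a synaptic membrane protein, fell from 20.3 ± 7.22 to 3.71 ± 2.52 CPM (-2.52 ± 0.47, adjusted p = 0.0198). Pcsk1n, an inhibitor of prohormone convertase 1, fell from 201 ± 90.4 to 39.0 ± 22.8 CPM (-2.39 ± 0.52, adjusted p = 0.0315). Nkx6-2, an oligodendrocyte homeobox factor (ENSMUSG00000041309, chromosome 7, 139579376 to 139582797), fell from 5.28 ± 0.274 to 1.29 ± 0.778 CPM (-2.12 ± 0.40, adjusted p = 0.0191). C1qtnf4 changed by -2.41 ± 0.55, Scand1 by -2.71 ± 0.52, Thbs4 by -2.84 ± 0.65, Syndig1l by -2.52 ± 0.61, Epo by -2.29 ± 0.49 and Gm13889 by -2.10 ± 0.43. Exons of Ptgfr, 4930447C04Rik, Scand1, Pcsk1n, Epo, Nkx6-2 and Gm13889 overlap another gene (Gm43618, Six6, Cnbd2, Eras, Gnb2, Inpp5a and Gm27027), and Vmn2r84 and Dnah7c belong to families of similar genes, so the assignment of their reads is uncertain. Transcript GC content was 29.8 to 48.8 percent in the named rises and 53.7 to 70.7 percent in the named falls.

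In all, 1705 of 14272 genes passed, 533 higher and 1172 lower in susceptible offspring, 170 of them by over 2-fold. DESeq2 called 2379. Library values did not overlap in 4718 genes (33.1 percent, where chance gives 10 percent). Across libraries, the rank correlation of expression (as deviation from the tissue mean) with transcript GC was 0.222 to 0.758 in controls, -0.647 to -0.220 in susceptible and -0.513 to 0.155 in resilient libraries. The called genes follow it, with a median GC of 42.6 percent in those that rose and 58.2 percent in those that fell. Control library 4 had the highest value of 13 of 13 olfactory bulb genes, with a median log2 excess of 3.25 over the other mPFC libraries. The count was 0 after removal of each library's GC trend (an alternative added after the data were seen), and 405 (155 higher and 250 lower, 205 shared with the original calls) after the same without control 4. It was also 0 with only the 2 groups compared, 4287 with 1 surrogate variable and 2949 with all 18 libraries. With 1 library left out it was 327 (control 3), 3700 (control 4), 890 (resilient 7), 882 (resilient 8), 0 (susceptible 15) and 6 (susceptible 16). With the GC trend removed, the precursor list's median was -0.25 (adjusted p = 0.0657; 0.0457 and still -0.25 with the length trend removed too), the mitochondrially encoded list's -0.02 (adjusted p = 0.887) and the dopamine list's -0.09 (adjusted p = 0.147), while the myelin median was -0.85 (adjusted p = 1.87e-20). Still passing, the ribosomal median was -0.12, the risk gene median 0.09 and the striatal and immediate early medians -0.35 each. Without control 4 as well, the precursor median was 0.03 (adjusted p = 0.726) and the striatal median -0.21 (adjusted p = 0.0516). Interferon (0.01, adjusted p = 0.736), cytokine (-0.11, adjusted p = 0.746) and complement genes (-0.31, adjusted p = 0.264) did not pass. Cell type lists that did not pass (adjusted p 0.264 to 0.931) had these medians below 0: excitatory -0.10, GABAergic -0.13, astrocyte -0.06, endothelial -0.09, mural -0.14, meningeal -0.19 (the test opposite), erythrocyte -0.06, choroid plexus -0.02 (the test opposite), thalamus -0.14 and amygdala-enriched -0.10 (the test opposite). Those at or above 0 were microglia 0.02 (mean -0.07, the test also opposite) and cortical layer 0.12.

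**Figure D1:**
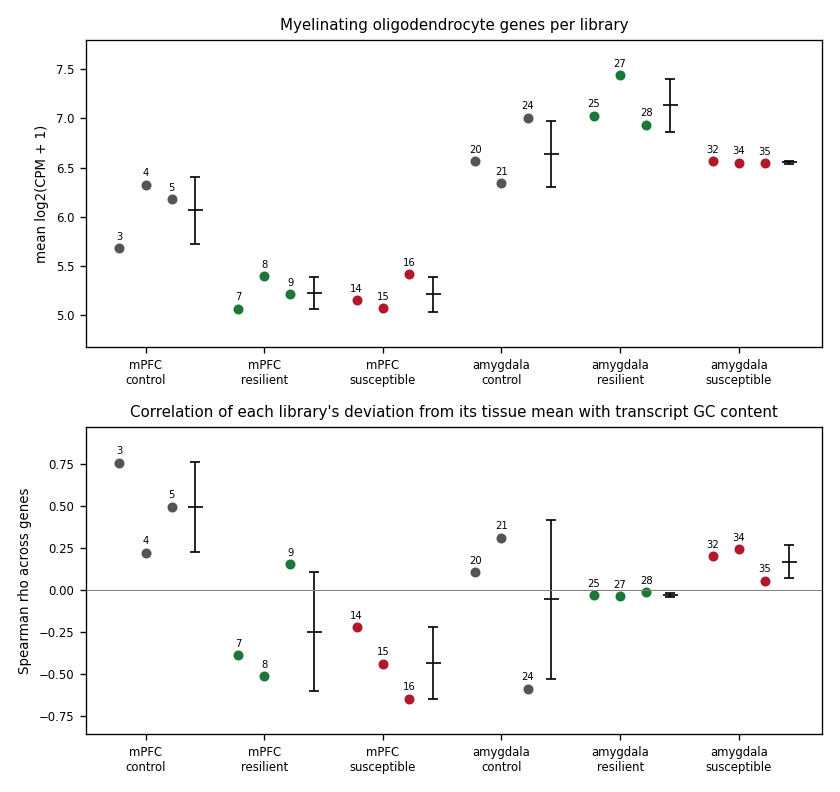
Each point is a library, labelled by its replicate number; bars are group mean ± SD (n = 3). Top: mean log2(CPM + 1) of the 22 myelinating oligodendrocyte genes; bottom: rank correlation of each library's deviation from its tissue mean with transcript GC content.

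In the mPFC of resilient offspring, myelin genes were lower than in controls as well (n = 3 per group). For the 9 lists that passed, adjusted p with an estimated correlation was 0.100 (neurodevelopmental risk genes) to 0.722. Mag fell by 1.22 ± 0.13 (adjusted p = 0.00787) and Mbp from 1717 ± 366 to 774 ± 109.6 CPM (-1.15 ± 0.16, adjusted p = 0.0172). Cldn11, the claudin of myelin tight junctions, fell from 79.5 ± 16.1 to 33.1 ± 7.67 CPM (-1.26 ± 0.22, adjusted p = 0.0406). Gjb1, a gap junction gene, fell by 1.5 ± 0.22. Of 22 members, 9 fell (19 over the list alone), with a median of -0.88, adjusted p = 1.42e-14. Hapln2 (-1.38 ± 0.19), Nkx2-2, a homeobox factor of the lineage (-1.42 ± 0.24), and Itgb4, an integrin (-1.39 ± 0.22), were also among the 10 largest falls. The others were Scand1 (-2.69 ± 0.50), ENSMUSG00000095742 on an unplaced scaffold (-2.22 ± 0.39), Gm27021 (-1.74 ± 0.31) and Gdf1 (-1.33 ± 0.23). The rises were smaller. Rasgrf2, a guanine nucleotide exchange factor, rose from 161 ± 15 to 232 ± 20.2 CPM (0.53 ± 0.11, adjusted p = 0.0485). Lcorl rose from 15.8 ± 2.13 to 26.5 ± 1.95 CPM (0.75 ± 0.12, adjusted p = 0.0348). The other 8 were Thsd4 (0.66), Nyap2 (0.61), Fam126b (0.55), Lnpep (0.55), Scai (0.50), Rabgap1l (0.47), Cc2d2a (0.46) and Grb10 (0.44). Exons of Scand1, Gm27021, Gdf1 and Lcorl overlap another gene, so these assignments are uncertain.

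Precursor genes fell in 2 of 12 cases (7 over the list alone), Olig1 by 1.11 ± 0.12 and Sox10 by 1.16 ± 0.15 (median -0.40, adjusted p = 0.000261). Ribosomal protein genes fell in 1 of 36 cases (11 over the list alone), Rps28 by 0.54 ± 0.11 (median -0.19, adjusted p = 9.65e-05). No member passed over all genes in the other 6 lists. Members over the list alone were 2 higher of 42 neurodevelopmental risk genes (median 0.18, adjusted p = 0.000208). They were 8 lower of 33 oxidative phosphorylation genes (median -0.14, adjusted p = 0.000565). They were 5 lower of 18 dopamine genes (median -0.28, adjusted p = 0.0231), and 5 lower of 15 striatal genes (median -0.51, adjusted p = 0.0231). They were 1 higher of 7 mitochondrially encoded genes (median 0.19, adjusted p = 0.0245). For type I interferon response genes they were 0 of 30 (median 0.23, adjusted p = 0.00361). Ifit3b, an interferon-induced gene, had 0.58 ± 0.25 (adjusted p = 0.193). Lists did not pass in these settings (adjusted p in brackets): interferon without control 3 (0.0862), control 5 (0.127, median 0.13) or resilient 8 (0.0705, median 0.11), dopamine without control 4 (0.0654) or control 5 (0.127), striatal without control 5 (0.115) or resilient 9 (0.05), oxidative phosphorylation without control 5 (0.0617), mitochondrial with no low-count filter (0.271) or without control 3 (0.106) or control 5 (0.127). With the GC trend removed the mitochondrial median was -0.02 (adjusted p = 0.809) and, still passing, the dopamine median -0.11, the striatal -0.32, the ribosomal -0.08 and the risk gene median 0.11. Without control 4 as well, the precursor (median -0.01, adjusted p = 0.495), striatal (-0.40, adjusted p = 0.109) and dopamine lists (-0.09, adjusted p = 0.187) did not pass, while the interferon median was 0.41 (adjusted p = 3.92e-08), and 0.48 with the length trend removed too. In all, 122 genes passed, 10 higher and 112 lower (3958 non-overlapping, 27.7 percent, where chance gives 10 percent). DESeq2 called 1001 (317 higher and 684 lower). The count was 943 (310 and 633) with all 18 libraries, 2464 with 1 surrogate variable, and 0 with only the 2 groups or with the GC trend removed. It was 239 (83 and 156) with the GC trend removed without control 4, and, with 1 library left out, 66 (control 3), 1738 (control 4), 392 (control 5), 0 (resilient 7), 0 (resilient 8), 11 (resilient 9) and 21 (susceptible 15). Short of the threshold (adjusted p 0.181 to 0.992), cell type medians below 0 were: excitatory -0.08, GABAergic -0.16, astrocyte -0.09, endothelial -0.08, mural -0.15, meningeal -0.31 (the test opposite), thalamus -0.19 and amygdala-enriched -0.13. Medians at or above 0 were microglia 0.03 (mean -0.05, the test also opposite), erythrocyte 0.07, choroid plexus 0.16 (mean -0.19) and cortical layer 0.16.

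Between susceptible and resilient offspring, immediate early genes were lower as a group in the mPFC of susceptible offspring (median -0.29, adjusted p = 3.52e-06). Type I interferon response genes were lower too (median -0.28, adjusted p = 2.47e-05). No member passed over all genes or over the list alone, and all 4 lists that passed had adjusted p = 0.902 with an estimated correlation. Ier2, an immediate early gene, stood at 3.78 ± 0.490 against 6.79 ± 0.676 CPM (-0.86 ± 0.22, adjusted p = 1) and Per1, a circadian repressor, at 75.2 ± 12.2 against 103 ± 6.31 CPM (-0.46 ± 0.12, adjusted p = 1). Of the interferon genes, Ifi35 had -0.60 ± 0.25, Ifit1 -1.03 ± 0.49 and Irf9 -0.32 ± 0.14. Heat shock genes were higher as a group (median 0.11, adjusted p = 0.00113), with no member passing. Mitochondrially encoded genes were too (median 0.15, adjusted p = 0.00316). Tfrc, the transferrin receptor, stood at 146 ± 10.7 against 119 ± 6.42 CPM (0.30 ± 0.08, adjusted p = 1). The remaining values chosen by the smallest p, none of which passed, were Ccnc 0.37, Fyttd1 0.27, Sptssb 0.89, Cox5a 0.23, Pprc1 -0.35, Tcf7l1 -1.18 and Zfp623 -0.40. No gene passed with edgeR or DESeq2, against 185 at an unadjusted p under 0.05 where 714 are expected by chance, and 1251 genes (8.77 percent, chance 10 percent) did not overlap. The lists did not pass (adjusted p in brackets) for interferon without resilient 8 (0.0545, median -0.18), for heat shock without resilient 9 (0.907, median 0.03), susceptible 14 (0.169) or susceptible 16 (0.137, median 0.05), and for mitochondrial genes without susceptible 16 (0.514, median 0.03) or with the GC trend removed (0.406, median 0.05). In the remaining cell types (adjusted p 0.124 to 0.961), medians below 0 were: precursor -0.01, microglia -0.03, mural -0.06, erythrocyte -0.25 and striatal -0.01. At or above 0 were excitatory 0.00 (mean -0.03, the test also opposite), GABAergic 0.04, astrocyte 0.03, myelin 0.04 (the test opposite), endothelial 0.01, meningeal 0.12, choroid plexus 0.04 (mean -0.06, the test also opposite), thalamus 0.02, cortical layer 0.01 (mean -0.02) and amygdala-enriched 0.03.

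With susceptible and resilient offspring pooled against controls, 18 of 22 myelin genes fell in the mPFC (22 over the list alone, median -0.88, adjusted p = 1.29e-12). So did 5 of 12 precursor genes (7 over the list alone, median -0.42, adjusted p = 0.000825). Both lists, like the ribosomal, oxidative phosphorylation and mitochondrially encoded lists below, had adjusted p = 0.640 with an estimated correlation. Of the risk genes 12 of 42 rose (18 higher and 3 lower over the list alone, median 0.19, adjusted p = 0.000653, adjusted p = 0.137 with an estimated correlation). The named rises include Glra3 (0.83 ± 0.16, adjusted p = 0.0112), Gm37899 (1.56 ± 0.34), Ptgfr (1.47 ± 0.41) and Vmn2r84 (1.39 ± 0.37). The falls include Nxph4 (-2.49 ± 0.35, adjusted p = 0.00566), Scand1 (-2.70 ± 0.40, adjusted p = 0.00701), Prr7 (-2.21 ± 0.36, adjusted p = 0.0103) and Epo, erythropoietin (-2.16 ± 0.38, adjusted p = 0.01). The remaining rises were Dnah7c 1.10, 4930447C04Rik 0.97, Ccdc113 0.82, Gm37928 0.78, Naaladl2 0.78 and Cenpw 0.78. The remaining falls were Thbs4 -2.50, C1qtnf4 -2.29, Pcsk1n -2.20, Syndig1l -2.18, Sp9 -2.16 and ENSMUSG00000095742 -2.13. Exons of Naaladl2 and Sp9 overlap Gm37136 and Cir1. Ribosomal protein genes fell in 13 of 36 cases (17 over the list alone), with a median of -0.19, adjusted p = 3.21e-05. Oxidative phosphorylation genes fell in 10 of 33 (11 lower and 1 higher over the list alone, median -0.11, adjusted p = 0.00528). Striatal genes fell in 4 of 15 (6 over the list alone, median -0.49, adjusted p = 0.0221, adjusted p = 0.393 with an estimated correlation). Dopamine genes fell in 5 of 18 (9 lower and 1 higher over the list alone, median -0.31, adjusted p = 0.0292, adjusted p = 0.497 with an estimated correlation). Mitochondrially encoded genes rose in 2 of 7 (3 over the list alone, median 0.23, adjusted p = 0.00528).

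In this pooled contrast 2281 genes passed, 734 higher and 1547 lower, and 2769 with DESeq2. The count was 3504 with all 18 libraries, 122 (17 higher and 105 lower) with the GC trend removed, 588 with the GC trend removed without control 4, and, with 1 library left out, 703 (control 3), 3938 (control 4), 782 (resilient 7), 709 (resilient 8), 1053 (susceptible 15) and 963 (susceptible 16). Cell type lists that did not pass (adjusted p 0.210 to 0.936) had these medians below 0: excitatory -0.09, GABAergic -0.15, astrocyte -0.08, endothelial -0.07, mural -0.08, meningeal -0.29 (the test opposite), erythrocyte -0.01, thalamus -0.19 and amygdala-enriched -0.07 (the test opposite). Those at or above 0 were microglia 0.04 (mean -0.06, the test also opposite), choroid plexus 0.10 (mean -0.22) and cortical layer 0.14. Of the genes called in both phenotypes, 9 rose in both, 111 fell in both and 0 went opposite ways, where 0.373 and 9.20 shared rises and falls are expected for independent calls. The 2 phenotypes' fold changes correlated at r = 0.893 (covariance 0.131). In 20 simulations of unchanged groups with shared controls r was 0.482 (covariance 0.0283), with at most 1 shared call. Regroupings of the real libraries reached 0.836, so this baseline can be too low. Part of the excess (0.103) can come from the 3 shared controls (variance over 3 of 0.0488), which cannot be split.

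In the amygdala of resilient offspring, striatal medium spiny neuron and myelin genes were higher than in controls and choroid plexus genes lower (n = 3 per group). The 7 lists that passed had adjusted p = 0.628 with an estimated correlation. Pdyn, which encodes prodynorphin, rose from 39.4 ± 8.77 to 75.3 ± 18.5 CPM (0.93 ± 0.20, adjusted p = 0.0435), the only striatal gene of 15 to pass over all genes. Over the list alone 14 passed, with a median of 1.16, adjusted p = 6.84e-09. Drd1, the D1 dopamine receptor, had 1.10 ± 0.35 and Tac1 0.89 ± 0.26 without passing. Mbp rose from 2353 ± 250.2 to 3581 ± 725 CPM (0.61 ± 0.13, adjusted p = 0.0402) and Hapln2 from 18.1 ± 0.913 to 29.6 ± 6.05 CPM (0.71 ± 0.14, adjusted p = 0.0263). Of 22 myelin genes 4 rose (11 over the list alone, median 0.47, adjusted p = 3.44e-09). Choroid plexus and ependyma genes gave a median of -1.48, adjusted p = 3.42e-06, with no member passing over all genes or the list alone (Tmem212 -1.66 ± 0.52, adjusted p = 0.122). Resilient library 27 had the highest striatal score of the 9 amygdala libraries (mean log2(CPM + 1) of 7.85 against 5.67 to 6.43 in controls) and the lowest choroid plexus score (2.06 against 4.75 to 5.11).

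Immediate early genes were higher: 5 of 28 rose and 0 fell (16 and 2 over the list alone, median 0.62, adjusted p = 7.75e-06). Egr1, an activity-induced zinc finger factor (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), rose from 143 ± 29.7 to 328 ± 96.0 CPM (1.20 ± 0.25, adjusted p = 0.0459). Ier5 rose from 28.6 ± 3.45 to 62.6 ± 13.5 CPM (1.13 ± 0.21, adjusted p = 0.0293) and Trib1 from 12.1 ± 1.09 to 26 ± 7.52 CPM (1.10 ± 0.20, adjusted p = 0.0207). Glucocorticoid-responsive genes gave a median of 0.26, adjusted p = 0.00171, with 3 higher and 1 lower of 23 (6 and 1 over the list alone). Arl4d, a small GTPase gene, rose from 11.5 ± 2.50 to 26.6 ± 1.46 CPM (1.21 ± 0.14, adjusted p = 0.00527), while Nr3c2, the mineralocorticoid receptor, fell by 0.91 ± 0.15 (adjusted p = 0.0176). The dopamine list was higher (median 0.76, adjusted p = 0.000959), with 11 members higher over the list alone. Its 1 member passing over all genes, the D5 receptor Drd5, fell by 1.40 ± 0.31 (adjusted p = 0.0383). Genes enriched in amygdala fell in 3 of 16 cases (6 over the list alone), Zbtb20 by 0.83 ± 0.15, Nr2f2 by 1 ± 0.19 and Etv1 by 0.55 ± 0.11 (median -0.43, adjusted p = 0.000930). Without control 24, the adjusted p of the glucocorticoid list was 0.0968. Without resilient 27 and susceptible 32, libraries set aside after the data were seen, the striatal median was 0.58, the dopamine median 0.39 and the choroid plexus median -0.96. Short of the threshold (adjusted p 0.0795 to 0.714), cell type medians below 0 were: excitatory -0.23 and meningeal -0.04. Medians at or above 0 were GABAergic 0.22, astrocyte 0.04, precursor 0.02, microglia 0.10, endothelial 0.13, mural 0.05, erythrocyte 0.10, thalamus 0.07, hypothalamus 0.01 (mean -0.02, the test also opposite) and cortical layer 0.32.

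Lhx9, a LIM homeobox factor (ENSMUSG00000019230, chromosome 1, 138825186 to 138848577), fell from 7.93 ± 4.25 to 0.166 ± 0.0782 CPM (-5.46 ± 0.63, adjusted p = 0.00779). Slc9a4, a sodium/proton exchanger (ENSMUSG00000026065, chromosome 1, 40580081 to 40630725), fell from 15.3 ± 7.64 to 0.451 ± 0.0713 CPM (-5.05 ± 0.66, adjusted p = 0.0125). Il16, a cytokine, fell from 19.4 ± 4.81 to 2.45 ± 0.603 CPM (-2.97 ± 0.34, adjusted p = 0.00779), and Thsd4 from 48.4 ± 18.7 to 7.20 ± 0.729 CPM (-2.75 ± 0.37, adjusted p = 0.0142). Fyb2 (-3.28 ± 0.37), Serpina3g (-4.08 ± 0.67), Syna (-4.03 ± 0.63), Spink8 (-3.35 ± 0.50), Itgbl1 (-3.08 ± 0.57) and Adamts14 (-2.70 ± 0.48) complete the 10. Rspo1, a secreted activator of Wnt signalling (ENSMUSG00000028871, chromosome 4, 124986430 to 125009099), rose from 0.699 ± 0.239 to 4.17 ± 1.32 CPM (2.58 ± 0.39, adjusted p = 0.0128). The other rises were Impg1 (2.32), Tmem200b (1.93), Krt80 (1.80), Rnf39 (1.68), Slfn2 (1.34), Nradd (1.31) and Trhr2, a receptor for thyrotropin-releasing hormone (1.22). Exons of Slc9a4 and Il16 overlap Gm37435 and Stard5, and Serpina3g and Slfn2 have close paralogs, so their reads are uncertain. Of 10 hippocampal genes, Spink8 among them, 6 were highest in control 20, with a median log2 excess over the other amygdala libraries of 0.86 in control 20, 0.69 in control 21 and 0.14 in control 24. In all, 355 of 14585 genes passed, 151 higher and 204 lower, 99 by over 2-fold, and 771 (399 and 372) with DESeq2. Library values did not overlap in 3175 (21.8 percent, chance 10 percent). The count was 103 with only the 2 groups, 790 with 1 surrogate variable, 538 with the GC trend removed, and, with 1 library left out, 36 (control 20), 198 (control 21), 740 (control 24), 188 (resilient 27), 31 (resilient 28) and 110 (susceptible 34). Without resilient 27 and susceptible 32 together it was 320, of which 197 were shared.

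**Figure D2:**
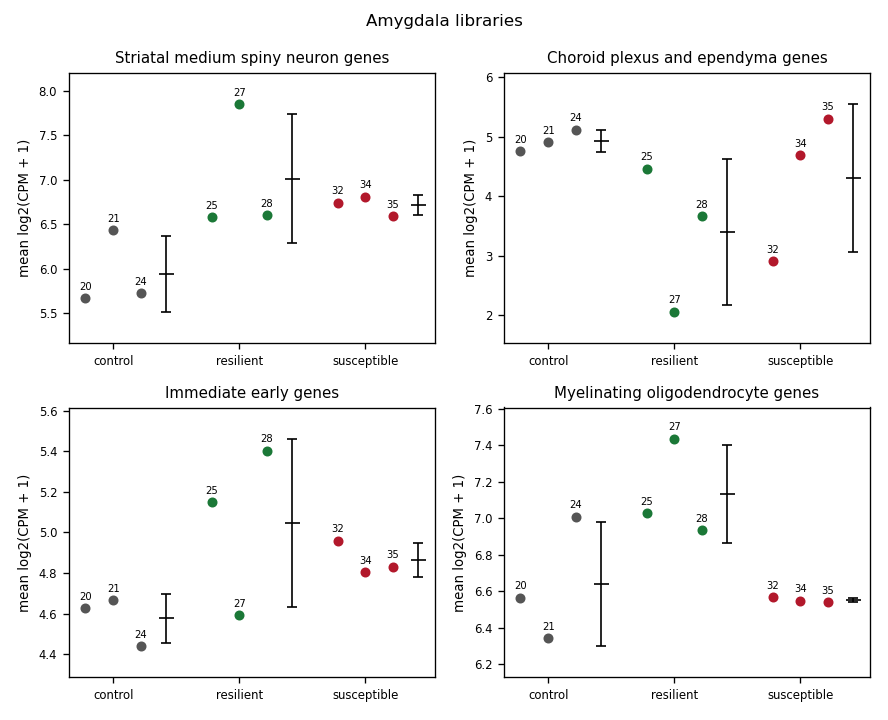
Mean log2(CPM + 1) of 4 gene lists (striatal medium spiny neuron, choroid plexus and ependyma, immediate early, myelinating oligodendrocyte) in each amygdala library, labelled by replicate number; bars are group mean ± SD (n = 3).

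In the amygdala of susceptible offspring, striatal genes (median 0.73, adjusted p = 7.02e-07) and immediate early genes (median 0.35, adjusted p = 0.000495) were higher as groups than in controls, each at adjusted p = 0.758 with an estimated correlation, with no member passing. Pdyn stood at 62.4 ± 9.22 against 39.4 ± 8.77 CPM (0.66 ± 0.20, adjusted p = 0.289). Dopamine (median 0.54, adjusted p = 0.00494, 1 higher and 1 lower over the list alone), cortical layer (median 0.22, adjusted p = 0.00597) and microglia genes (median 0.17, adjusted p = 0.00597, 1 higher over the list alone) were higher too, each at adjusted p = 0.758 with an estimated correlation. Tmem119, a microglial membrane protein, had 0.50 ± 0.12, adjusted p = 0.148. Erythrocyte genes (median 0.68, adjusted p = 0.0186, adjusted p = 0.758 with an estimated correlation, 4 higher over the list alone) included the globin Hbb-bt, which has near-identical paralogs (0.95 ± 0.21, adjusted p = 0.123). Synaptic vesicle and adhesion (median 0.09, adjusted p = 0.00597) and endothelial genes (median 0.11, adjusted p = 0.0243) were higher as groups, each at adjusted p = 0.758 with an estimated correlation. Heat shock genes gave a median of 0.14, adjusted p = 0.0243, adjusted p = 0.825 with an estimated correlation. Glucocorticoid-responsive genes were higher (median 0.15, adjusted p = 0.0245, adjusted p = 0.758 with an estimated correlation, 3 higher and 1 lower over the list alone). Cytokine genes gave a median of 0.14, adjusted p = 0.0473, adjusted p = 0.758 with an estimated correlation (1 higher over the list alone, Cx3cl1 0.41 ± 0.09). By smallest p, Plxnd1, a semaphorin receptor, stood at 163 ± 6.40 against 101 ± 16.4 CPM (0.69 ± 0.10, adjusted p = 0.109) and Arhgef26 at 27.8 ± 4.56 against 47.3 ± 4.75 CPM (-0.74 ± 0.12, adjusted p = 0.109). Other values that did not pass were Rhobtb2 0.53, Pdzd2 0.71, Fam163b 0.51, Rasgef1c 0.49, Gm32444 -1.07, Srsf5 -0.50, Faim -0.66 and Nrip3 -0.65.

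No gene passed with edgeR in this comparison (smallest adjusted p = 0.109). Unadjusted, 1609 were under 0.05 (729 expected by chance), and DESeq2 called 155. Library values of 2484 genes (17.0 percent, chance 10 percent) did not overlap. The count was 8 with no low-count filter, 3 with all 18 libraries, and, with 1 library left out, 3 (control 21) and 34 (control 24). Cortical layer and microglia genes did not pass without control 20 (adjusted p = 0.0504 for each). Others did not pass as follows: synaptic without control 24 (0.0598), susceptible 32 (0.0652) or resilient 27 and susceptible 32 (0.0562), or with the GC and length trends removed (0.0504), erythrocyte without control 21 (0.138) or susceptible 35 (0.0671), glucocorticoid without control 24 (0.315) or susceptible 34 (0.0853, median 0.09) and heat shock without control 20 (0.172, median 0.09), control 21 (0.0577), susceptible 32 (0.0694) or susceptible 34 (0.143). Endothelial genes did not pass without control 21 (0.0577), control 24 (0.0907), susceptible 34 (0.271, median 0.03) or susceptible 35 (0.0804), and cytokine genes with no low-count filter (0.0600), with the GC trend removed (0.106) or without control 20 (0.0810), control 21 (0.0846), control 24 (0.0907), resilient 25 (0.0554), resilient 27 (0.0877), resilient 28 (0.0561), susceptible 34 (0.159) or susceptible 35 (0.0832). Myelin (-0.10, adjusted p = 0.420) and interferon genes (-0.02, adjusted p = 0.999) did not pass. In the remaining cell types (adjusted p 0.0878 to 0.781), medians below 0 were: astrocyte -0.02 (mean 0.01, the test also opposite), myelin -0.10, choroid plexus -0.22, hypothalamus -0.24 and amygdala-enriched -0.10. At or above 0 were excitatory 0.07, GABAergic 0.09, precursor 0.02, mural 0.10, meningeal 0.28 and thalamus 0.02 (mean -0.01).

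Against resilient offspring, myelin genes were lower in the amygdala of susceptible offspring as a group (median -0.59, adjusted p = 1.55e-14). For the 9 lists that passed, adjusted p with an estimated correlation was 0.641 to 0.768. No myelin gene passed over all genes, and 20 of 22 were lower over the list alone. Hapln2 stood at 17.4 ± 2.05 against 29.6 ± 6.05 CPM (-0.78 ± 0.14, adjusted p = 0.206). Synaptic vesicle and adhesion genes were higher (median 0.15, adjusted p = 2.33e-05), as were excitatory neuron genes (median 0.26, adjusted p = 0.00503). Glutamate receptor genes were higher (median 0.10, adjusted p = 0.0183, 1 over the list alone). Axon guidance genes were higher (median 0.12, adjusted p = 0.00748, 4 over the list alone), and so were amygdala-enriched genes (median 0.21, adjusted p = 0.0183). Choroid plexus (median 1.12, adjusted p = 0.000834) and meningeal fibroblast genes (median 0.92, adjusted p = 0.0113) were higher. Erythrocyte genes were higher too (median 0.50, adjusted p = 0.0142, 5 over the list alone). Mas1, an angiotensin peptide receptor, stood at 22.6 ± 2.89 against 10.5 ± 1.67 CPM (1.12 ± 0.16, adjusted p = 0.166) and Ccn3 at 163 ± 26 against 86.4 ± 14.8 CPM (0.92 ± 0.14, adjusted p = 0.206). Syn2, a synaptic vesicle protein, stood at 745 ± 24.7 against 545 ± 60.6 CPM (0.45 ± 0.09, adjusted p = 0.206). Pvalb, a calcium buffer of fast-spiking interneurons, stood at 16 ± 4.61 against 39.8 ± 10.9 CPM (-1.37 ± 0.21, adjusted p = 0.206). The other values by smallest p were Timp2 0.38, Kcnd3 0.44, Sec14l5 -0.78, Clk1 -0.42 and Cdk5rap2 -0.58. Resilient library 27 had an excitatory neuron score of 5.94, and the choroid plexus score was 2.06 in it and 2.91 in susceptible library 32.

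No gene passed with edgeR between these phenotypes (smallest adjusted p = 0.166), against 1830 at an unadjusted p under 0.05 (729 expected by chance) and 111 called by DESeq2. Non-overlapping genes numbered 2985 (20.5 percent, chance 10 percent). The count was 1 with no low-count filter or with only the 2 groups, 14 with 1 surrogate variable, 44 without resilient 27 and susceptible 32, and, with 1 library left out, 5 (control 24) and 36 (susceptible 32). With a library left out, lists did not pass as follows (adjusted p in brackets): choroid plexus without resilient 27 (0.331, median 0.69) or susceptible 35 (0.104, median 0.54), excitatory without resilient 27 (0.124, median 0.11) or susceptible 32 (0.0624). The same holds for meningeal genes without resilient 25 (0.0538), resilient 27 (0.146), susceptible 34 (0.101) or susceptible 35 (0.184, median 0.58), erythrocyte without resilient 25 (0.0561), susceptible 34 (0.0515) or susceptible 35 (0.0719), glutamate receptor without resilient 28 (0.0795, median 0.06), susceptible 32 (0.0624) or susceptible 34 (0.0558), amygdala-enriched without resilient 28 (0.0795) or susceptible 34 (0.158). Without resilient 27 and susceptible 32 the excitatory median was 0.05 (adjusted p = 0.485) and the synaptic median 0.05 (adjusted p = 0.0835). Cell type lists that did not pass (adjusted p 0.0848 to 0.944) had these medians below 0: GABAergic -0.07, astrocyte -0.04, precursor -0.03, striatal -0.38, thalamus -0.10 and hypothalamus -0.05 (the test opposite). Those at or above 0 were microglia 0.06, endothelial 0.00 (mean 0.01, the test also opposite), mural 0.03 and cortical layer 0.06.

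With the phenotypes pooled against controls in the amygdala, Gabrd, the delta subunit of extrasynaptic GABA receptors (ENSMUSG00000029054, chromosome 4, 155384980 to 155398112), was higher, at 65.6 ± 4.76 in susceptible and 81.9 ± 16.1 in resilient against 40.9 ± 8.68 CPM in control offspring (0.84 ± 0.14, adjusted p = 0.0252). Lhx9 was lower, at 1.67 ± 1.07 in susceptible and 0.166 ± 0.0782 in resilient against 7.93 ± 4.25 CPM in control offspring (-3.77 ± 0.43, adjusted p = 0.00733). Arl4d rose by 0.95 ± 0.13, adjusted p = 0.00932, Rspo1 by 1.99 ± 0.38, adjusted p = 0.0313 and Pdp1, a pyruvate dehydrogenase phosphatase, by 0.81 ± 0.12, adjusted p = 0.0149. The other rises were Sphk1 1.25, Tfcp2l1 0.95, Gm45623 0.88, Hr 0.84, Sgpp2 0.82 and Stard10 0.73. Il16 fell by 2.23 ± 0.26, Thsd4 by 2.17 ± 0.29 and Chrm5, a muscarinic receptor, by 2.29 ± 0.44. The other falls were Slc9a4 -3.80, Syna -2.88, Spink8 -2.53, Adamts14 -2.38, Fyb2 -2.34 and Itgbl1 -2.31. Exons of Sgpp2 overlap Farsb.

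Striatal genes were higher in the pooled contrast, 13 of 15 over the list alone and 0 over all genes (median 0.93, adjusted p = 2.42e-09). All 13 lists that passed here had adjusted p = 0.740 with an estimated correlation. Immediate early genes were higher, 1 over all genes and 14 of 28 over the list alone (median 0.53, adjusted p = 5.66e-06), and choroid plexus genes lower with no member passing (median -0.82, adjusted p = 0.000245). Myelin (median 0.20, adjusted p = 0.00117), cortical layer (median 0.25, adjusted p = 0.0111) and microglia genes (median 0.11, adjusted p = 0.0146) were higher as groups. So were glucocorticoid-responsive genes (2 higher and 1 lower over all genes, 7 and 1 over the list alone, median 0.23, adjusted p = 0.00252). Dopamine genes were higher as a group (median 0.65, adjusted p = 0.000582), although 1 member fell and 0 rose over all genes (1 and 1 over the list alone). Amygdala-enriched genes fell in 2 cases (5 over the list alone, median -0.20, adjusted p = 0.00580). Endothelial (median 0.10, adjusted p = 0.0214), cytokine (median 0.14, adjusted p = 0.0319), heat shock (median 0.13, adjusted p = 0.0337) and GABAergic interneuron genes (median 0.14, adjusted p = 0.0475) were higher as groups. In all, 217 genes passed, 80 higher and 137 lower, and 528 (294 and 234) with DESeq2. The count was 338 with the GC trend removed, 141 without resilient 27 and susceptible 32, and, with 1 library left out, 16 (control 20), 144 (control 21), 447 (control 24), 61 (resilient 28), 61 (susceptible 32), 26 (susceptible 34) and 140 (susceptible 35). The 2 phenotypes' fold changes correlated at r = 0.612 (covariance 0.0620), against 0.491 (covariance 0.0221) simulated as for mPFC. Regroupings reached 0.894, with the same limit. Part of the excess (0.0399) can come from the 3 shared controls (variance over 3 of 0.0195), which cannot be split. Short of the threshold (adjusted p 0.142 to 0.864), cell type medians below 0 were: excitatory -0.10 (mean 0.00), astrocyte -0.05 (mean 0.03, the test also opposite) and hypothalamus -0.14. Medians at or above 0 were precursor 0.02, mural 0.08, meningeal 0.13 (mean -0.01, the test also opposite), erythrocyte 0.37 and thalamus 0.04.

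The resilient-control difference itself differed between tissues, tested as the amygdala effect minus the mPFC effect. Sox10 (ENSMUSG00000033006, chromosome 15, 79154908 to 79165240) stood at 49.7 ± 4.51 against 35.9 ± 3.53 CPM in amygdala and 15.9 ± 1.74 against 35.4 ± 6.81 CPM in mPFC (1.62 ± 0.18, adjusted p = 0.000755). Hapln2 differed by 2.09 ± 0.24, adjusted p = 0.000755, Prr18, an oligodendrocyte gene, by 1.62 ± 0.21, adjusted p = 0.000964, and Cntn2, a contactin of the axon beside the node, by 0.94 ± 0.12, adjusted p = 0.000964. Thsd4 went the other way, at -3.41 ± 0.40, adjusted p = 0.000964. Lists whose effect was higher in amygdala than in mPFC follow; with an estimated correlation, adjusted p was 0.313 to 0.613 for the lists that passed. Myelin genes (15 higher and 0 lower of 22, 21 and 0 over the list alone) gave a median of 1.36, adjusted p = 8.75e-19. Striatal genes (5 higher and 0 lower of 15, 13 and 0 over the list alone) gave a median of 1.71, adjusted p = 2.02e-07. Dopamine genes (3 higher and 0 lower of 19, 12 and 1 over the list alone) gave a median of 1.13, adjusted p = 0.000534. Immediate early genes (2 higher and 0 lower of 29, 8 and 1 over the list alone) gave a median of 0.67, adjusted p = 0.00172. Precursor genes (2 higher and 0 lower of 12, 5 and 0 over the list alone) gave a median of 0.46, adjusted p = 0.00156. GABAergic interneuron genes (2 higher and 0 lower of 13, 4 and 1 over the list alone) gave a median of 0.48, adjusted p = 0.0290. Ribosomal protein genes (1 higher and 0 lower of 36, 6 and 0 over the list alone) gave a median of 0.18, adjusted p = 0.00263. Oxidative phosphorylation genes (0 of 33, also over the list alone) gave a median of 0.16, adjusted p = 0.00156. Glucocorticoid-responsive genes (3 higher and 0 lower of 24, 5 and 1 over the list alone) gave a median of 0.34, adjusted p = 0.0256. The effect was lower in amygdala for 2 lists. Neurodevelopmental risk genes (0 higher and 2 lower of 42, 0 and 4 over the list alone) gave a median of -0.09, adjusted p = 0.0167. Choroid plexus genes (0 of 18, also over the list alone) gave a median of -1.43, adjusted p = 0.000567, many of them at 3 counts or fewer in a whole mPFC group. In all 680 of 14828 genes passed, 440 higher and 240 lower, and 1249 (813 and 436) with DESeq2. The count was 321 (161 and 160) with the GC trend removed, 1135 without mPFC control 4, amygdala resilient 27 and amygdala susceptible 32, and, with 1 library left out, 386 (amygdala control 20), 433 (amygdala control 24), 1424 (mPFC control 4), 349 (amygdala resilient 27), 414 (amygdala resilient 28), 240 (mPFC resilient 7) and 257 (mPFC resilient 8).

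The susceptible-control difference also differed between tissues. Vps37b, an ESCRT-I subunit, differed by 1.34 ± 0.16, adjusted p = 0.00153. Egr4, an immediate early gene, stood at 10.6 ± 1.12 against 7.43 ± 2.38 CPM in amygdala and 8.34 ± 1.72 against 26.5 ± 5.83 CPM in mPFC (2.18 ± 0.30, adjusted p = 0.00344). Tsc22d4 differed by 1.15 ± 0.14, adjusted p = 0.00153, Phospho1 by 1.30 ± 0.17, adjusted p = 0.00344 and Sox10 by 1.36 ± 0.19, adjusted p = 0.00344. Exons of Vps37b and Phospho1 overlap other genes (Gm37939 and Hip1r, Abi3 and Zfp652). In 6 lists the effect was higher in amygdala, each at adjusted p = 0.629 with an estimated correlation. Myelin genes (8 higher and 0 lower of 22, 13 and 0 over the list alone) gave a median of 0.75, adjusted p = 3.74e-07. Striatal genes (2 higher and 0 lower of 15, 5 and 0 over the list alone) gave a median of 1.15, adjusted p = 7.20e-05. Immediate early genes (5 higher and 0 lower of 29, 5 and 0 over the list alone) gave a median of 0.75, adjusted p = 0.000223. Dopamine genes (2 higher and 0 lower of 19, 5 and 0 over the list alone) gave a median of 0.84, adjusted p = 0.00340. Precursor genes (2 higher and 0 lower of 12, 4 and 0 over the list alone) gave a median of 0.50, adjusted p = 0.00387. Ribosomal protein genes (9 higher and 0 lower of 36, 14 and 1 over the list alone) gave a median of 0.17, adjusted p = 0.00427. In all 1267 genes passed, 837 higher and 430 lower in this difference, and 1853 with DESeq2. The count was 0 with the GC trend removed within each tissue, 2227 without the 3 libraries named above, and, with 1 library left out, 836 (amygdala control 20), 313 (amygdala control 24), 520 (mPFC control 3), 2437 (mPFC control 4), 583 (amygdala susceptible 32), 143 (amygdala susceptible 34), 801 (amygdala susceptible 35), 516 (mPFC susceptible 15) and 99 (mPFC susceptible 16).

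For the susceptible-resilient difference between tissues no gene passed with edgeR or DESeq2, against 844 at an unadjusted p under 0.05 (741 expected by chance), and 9 passed without the 3 libraries named above. As a group, myelin genes differed downward (median -0.62, adjusted p = 1.39e-10). The other 7 lists that passed differed upward; with an estimated correlation, adjusted p was 0.359 to 0.870 for all 8. Choroid plexus genes gave a median of 1.05, adjusted p = 0.00209. Erythrocyte genes (2 higher over the list alone) gave a median of 0.74, adjusted p = 0.00330. Synaptic genes gave a median of 0.14, adjusted p = 0.00586. Axon guidance genes gave a median of 0.09, adjusted p = 0.0292. Excitatory neuron genes gave a median of 0.32, adjusted p = 0.0312. Glutamate receptor genes gave a median of 0.09, adjusted p = 0.0359. Wnt signalling genes gave a median of 0.12, adjusted p = 0.0435. The cell type lists that did not pass follow. For resilient-control (adjusted p 0.139 to 0.937), medians below 0 were: excitatory -0.07 and amygdala-enriched -0.27 (mean 0.07). Those at or above 0 were astrocyte 0.15, microglia 0.12, endothelial 0.12, mural 0.18, meningeal 0.18 (mean -0.05, the test also opposite), erythrocyte 0.16 (the test opposite), thalamus 0.21, hypothalamus 0.55 and cortical layer 0.22 (the test opposite). For susceptible-control (adjusted p 0.0817 to 0.936), medians below 0 were: choroid plexus -0.18. Those at or above 0 were excitatory 0.14, GABAergic 0.39, astrocyte 0.09, microglia 0.16, endothelial 0.20, mural 0.13, meningeal 0.38 (the test opposite), erythrocyte 0.90, thalamus 0.25, hypothalamus 1.07, cortical layer 0.05 and amygdala-enriched 0.11 (the test opposite). For susceptible-resilient (adjusted p 0.190 to 0.845), medians below 0 were: GABAergic -0.03, astrocyte -0.08, precursor -0.02, striatal -0.26, thalamus -0.14 and hypothalamus -0.06 (the test opposite). Those at or above 0 were microglia 0.10, endothelial 0.03, mural 0.19, meningeal 0.63, cortical layer 0.08 and amygdala-enriched 0.22.

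Between tissues in control offspring, choroid plexus, striatal and amygdala-enriched genes were higher in amygdala (n = 3 per tissue). For the 9 lists that passed, adjusted p with an estimated correlation was 0.471 to 0.572. Ttr, transthyretin, a secretory product of choroid plexus (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321), stood at 2526 ± 640.3 against 0.312 ± 0.380 CPM (12.91 ± 1.94, adjusted p = 0.000877). Of 18 choroid plexus genes 17 were higher (17 over the list alone, median 5.69, adjusted p = 2.08e-16). Calml4 (8.06 ± 1.08, adjusted p = 0.000257) and the folate receptor Folr1 (7.91 ± 1.33, adjusted p = 0.00140) are further rises. Tmem212 and Ccdc180 had no count in mPFC controls and were at least 45.5-fold and 44.0-fold higher, bounds set by 3 counts over the group; with Tmem212 at its bound the list median is 5.54. Of 15 striatal genes 12 were higher (13 over the list alone, median 1.64, adjusted p = 2.39e-11). Among them are the adenosine receptor Adora2a (4.13), the D2 receptor Drd2 (3.88), Penk (2.71), Drd1 (1.64), Rarb (1.46), Gpr6 (2.90), Rgs9 (1.82), Ppp1r1b (1.52), Syndig1l (2.40), Pde10a (1.52) and Tac1 (1.21). Of the amygdala-enriched genes Cyp26b1, a retinoic acid hydroxylase (2.02 ± 0.18, adjusted p = 1.25e-05), Nr2f2 (2.52 ± 0.25), Dlk1 (3.18 ± 0.38), Gpr101 (3.28 ± 0.41), Prkcd (0.99 ± 0.20), Zbtb20 (1.06 ± 0.30) and Etv1 (0.51 ± 0.10) were higher and Adcyap1 (-1.73 ± 0.31) lower. The list (7 higher and 1 lower of 16, 8 and 2 over the list alone) gave a median of 0.29, adjusted p = 0.0145. Hypothalamus genes were higher in 3 of 5 cases (Nkx2-1 3.12 ± 0.65, Peg10 0.83 ± 0.18, Hap1 0.64 ± 0.18). Over the list alone 4 were higher, with a median of 0.83, adjusted p = 0.0119.

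Of the excitatory neuron genes, the transcription factors Emx1 (-1.32 ± 0.28) and Tbr1 (-0.69 ± 0.18) and the vesicular glutamate transporter Slc17a7 (-0.54 ± 0.15) were higher in mPFC, though the list did not pass. Of the cortical layer genes Stard8 (-1.38 ± 0.22) and Syt6 (-0.86 ± 0.28) were higher in mPFC and Nr4a2 (2.17 ± 0.42) and Otof (1.63 ± 0.37) in amygdala. Of the thalamus genes Adarb1 (-0.40 ± 0.07) was higher in mPFC and Slitrk6 (1.84 ± 0.56) in amygdala. The largest falls were Th, tyrosine hydroxylase (1.17 ± 0.235 against 19.3 ± 28.8 CPM; -4.04 ± 1, adjusted p = 0.0123), Lgr6 (-3.35 ± 0.81), Sphk1 (-2.83 ± 0.52), Doc2g (-2.82 ± 0.81) and Scand1 (-2.54 ± 0.44); the exons of Doc2g and Scand1 overlap Gm49405 and Cnbd2. For Th, Lgr6 and Doc2g the SD in mPFC controls exceeds the mean, through control 4, the library with the highest values of the olfactory bulb genes. Of the lists, 3 were lower in amygdala. Immediate early genes (1 higher and 16 lower of 29, 1 and 18 over the list alone) gave a median of -0.86, adjusted p = 3.12e-07. Synaptic vesicle genes (1 higher and 9 lower of 33, 1 and 12 over the list alone) gave a median of -0.23, adjusted p = 0.000594. Oxidative phosphorylation genes (0 higher and 10 lower of 33, 0 and 13 over the list alone) gave a median of -0.13, adjusted p = 0.000230. Myelin and dopamine genes were higher. The former (9 higher and 0 lower of 22, 19 and 0 over the list alone) gave a median of 0.61, adjusted p = 3.74e-06. The latter (10 higher and 2 lower of 19, 12 and 3 over the list alone) gave a median of 0.70, adjusted p = 0.000243. In all 2778 of 14828 genes passed, 1308 higher in amygdala and 1470 lower, 718 by over 2-fold, and 3045 with DESeq2. Library values did not overlap in 4229 (28.5 percent, chance 10 percent). The log2 changes correlated with transcript GC at -0.471 (rank), with a median GC of 47.2 percent in the higher and 56.6 percent in the lower genes; the GC trend was not removed here. The count was 5096 without the 3 libraries named above, and, with 1 library left out, 1400 (amygdala control 24), 1509 (mPFC control 3) and 4830 (mPFC control 4). In the remaining cell types (adjusted p 0.0943 to 0.834), medians below 0 were: excitatory -0.40, GABAergic -0.29, precursor -0.09, endothelial -0.12, mural -0.10, meningeal -0.59, erythrocyte -0.29 and cortical layer -0.02 (mean 0.08, the test also opposite). At or above 0 were astrocyte 0.05, microglia 0.01 (the test opposite) and thalamus 0.36.

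Of the 36 lists, 8 passed in none of the 12 comparisons, with these ranges of adjusted p: astrocyte (0.263 to 0.847), mural cell (0.418 to 0.748), thalamus (0.373 to 0.874), complement and MHC class I (0.111 to 0.800), serotonin signalling (0.149 to 0.999), GABA receptor and inhibitory synapse (0.264 to 0.834), neuropeptide (0.0654 to 0.837) and perineuronal net and matrix (0.173 to 0.843). The sex chromosome list held fewer than 5 tested genes and was not tested as a list; the Y-linked gene Ddx3y was present in all 18 libraries, at 33.4 to 74.3 CPM.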

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

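All tests of explanations below were chosen after the result was seen, except the library splits. The results listed here are those where a difference between tissues in the same contrast was itself tested and passed.

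For susceptible against control offspring, 1267 genes differed between tissues, with Egr4 at 2.18, Sox10 at 1.36, Vps37b at 1.34, Phospho1 at 1.30 and Tsc22d4 at 1.15 (log2, amygdala effect minus mPFC effect). With the GC trend removed within each tissue, no gene passed. Of 100 splits of the libraries drawn at random, 3 gave as many genes, the real one included, and the highest other gave 1939. Among the first 40 drawn, 3 had done so, and the draw was then extended to 100, which brought the share under 0.05. Both other such splits kept the real mPFC grouping. For resilient against control offspring, 680 genes differed between tissues, with Hapln2 at 2.09, Sox10 at 1.62, Prr18 at 1.62, Cntn2 at 0.94 and Thsd4 at -3.41, and 321 with the GC trend removed. Only the real split of 100 gave as many (highest other 467), but just 7 others kept the mPFC grouping, too few to judge chance.

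The first pattern weighed is the number of genes called in mPFC between susceptible offspring and controls (1705). A GC content trend that differs between libraries may account for much of it: with the trend removed, the median called gene kept 39.3 percent of its log2 change, from 0.53 to 0.20, and no gene passed although the median standard error went from 0.123 to 0.0987. Without control 4, 8.19 percent of that fit's own calls (303 of 3700) passed after removing the trend. This leaves open whether it caused all 1705. The 3700 calls without control 4 do not show how many of the 1705 come from its olfactory bulb tissue. A biological effect of phenotype stays open and untested, because the GC trend runs along the groups.

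The second pattern is the lower level of myelin genes in mPFC of susceptible offspring. With the GC trend removed the list median was -0.85 and the list still passed, which argues against that trend as its whole cause, and without control 4 as well it was -0.69, which argues against that library's tissue. A smaller share of white matter in the punch remains a candidate explanation: 100 percent of the 22 members were below 0 after the GC adjustment, from -1.15 to -0.54, as a common dilution would give. A change in oligodendrocytes themselves predicts the same and stays open.

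The third pattern is the set of genes called in amygdala between resilient offspring and controls (355), where library 27 stood apart. With the striatal, choroid plexus or hippocampal score of each library as a covariate, the median call outside the list kept 81.2, 84.5 and 54.3 percent of its log2 change, with median standard errors of 28, 24.7 and 31.4 percent. These cannot be told apart from a tissue share: 55.7, 36.5 and 66.9 percent of the variance of these scores lies between groups, and with each covariate no call passed as the standard error grew from 0.131 to 0.176, 0.156 and 0.199. The condition that a value exceed its bound of 75 percent by more than its standard error was added after these values were seen; under the first wording the striatal and choroid plexus values would have counted against those explanations. Striatal tissue as the whole source of the higher immediate early genes is argued against: within groups their score changed by -0.35 per unit of striatal score (95 percent limits -0.79 to 0.0830) where the resilient-control difference needs 0.44, and without library 27 the upper limit was 0.73 where 1.07 is needed, a test that replaced the list median without libraries 27 and 32 (0.75), which left out only 1 resilient library.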

How the results depend on the processing

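The alternatives that remove GC trends or set aside doubted libraries were chosen after seeing the data; the others were planned, and each range below leaves out 1 library at a time. No rule-chosen gene reversed (other list members unchecked). The chosen genes kept their side of the threshold in 644 planned comparisons, lost the call in 74 and gained it in 36. Added alternatives gave 275, 212 and 3, and omitting a library 1129, 387 and 14. No paired analysis was possible because the replicate numbers differ between tissues. The cause was not tested unless stated. With the GC trend removed, 153, 2 and 241 called genes had the other sign in mPFC (susceptible-control, resilient-control, both together), and 233, 4 and 364 without control 4 as well. The mitochondrially encoded medians changed sign in both phenotypes, and the susceptible precursor median did without control 4, none passing.

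In mPFC, susceptible against control (1705 genes) gave 0 with only the 2 groups, 2949 with all 18 libraries, 4287 with 1 surrogate variable, 0 with the GC trend and 0 with the GC and length trends removed, 405 and 357 with these removed without control 4, and 0 to 3700 with a library left out. Resilient against control (122) gave 1001 with DESeq2, 0 with only the 2 groups, 943 with all 18 libraries, 2464 with 1 surrogate variable, 0 and 0 with the trends removed, 239 and 198 without control 4 as well, and 0 to 1738. Susceptible against resilient (0) stayed at 0 in every setting run, 0 to 0. Both phenotypes together (2281) gave 3504 with all 18 libraries, 122 and 36 with the trends removed, 588 and 526 without control 4 as well, and 703 to 3938.

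In amygdala, susceptible against control (0 with edgeR, 1609 at an unadjusted p under 0.05) gave 155 with DESeq2, 8 with no low-count filter, 3 with all 18 libraries and 0 to 34. Resilient against control (355) gave 771 with DESeq2, 103 with only the 2 groups, 790 with 1 surrogate variable, 538 and 552 with the trends removed, and 31 to 740. Susceptible against resilient (0, and 1830 unadjusted) gave 111 with DESeq2, 1 with no low-count filter, 1 with only the 2 groups, 14 with 1 surrogate variable, 44 without libraries 27 and 32, and 0 to 36. Both together (217) gave 528 with DESeq2, 338 with the GC trend removed, 141 without libraries 27 and 32, and 16 to 447.

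Tissue differences gave, for susceptible against control (1267), 0 with the GC trend removed, 2227 without the 3 doubted libraries and 99 to 2437. For resilient against control (680) they gave 1249 with DESeq2, 321 with the GC trend removed, 1135 without the 3 libraries and 240 to 1424, and for susceptible against resilient (0) 9 without the 3 libraries and 0 to 0. Controls between tissues (2778) gave 5096 without the 3 libraries and 1400 to 4830.

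With an estimated correlation 0 lists passed in each of the 6 comparisons. With a library left out, 5 to 9, 4 to 10 and 3 to 8 lists passed in mPFC (susceptible-control, resilient-control, susceptible-resilient; 9, 9 and 4 otherwise) and 7 to 11, 6 to 13 and 5 to 12 in amygdala (11, 7 and 9 otherwise). Without libraries 27 and 32, 13 and 14 passed in amygdala for resilient-control and susceptible-resilient. The correlation of the 2 phenotypes in mPFC (0.893) was 0.627 with no low-count filter, 0.838 and 0.837 with the trends removed, 0.794 and 0.793 without control 4 as well, and 0.832 to 0.911; in amygdala (0.612) it was 0.481 with no filter, 0.503 without libraries 27 and 32, and 0.490 to 0.673. No setting equalised depth; the smallest mPFC and amygdala libraries held 7639338 and 5587054 counts.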

Other observations

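Every value of this part was examined after the data were seen, except the splits, which were planned. Olfactory bulb genes stood out in mPFC control 4: Eomes, a transcription factor of bulb output neurons, reached 20.4 CPM (302 counts) and Cdhr1, a cadherin of the same cells, 140.2 CPM, while Eomes was at most 2.32 CPM in the other mPFC libraries. The excitatory neuron score of that library was 6.35 against 7.16 and 7.05 in the other controls. Its first principal component (51.4 percent of variance) was 45.5 against -9.07 to -1.31 in the other mPFC libraries. In amygdala the first component (53.3 percent) was 34.3 in resilient 27, 19.5 in susceptible 32, 10.8 in resilient 28 and -17.7 to -13.0 in controls.

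Calls in mPFC of susceptible offspring and in amygdala of resilient offspring shared 5 rises and 6 falls, against 5.63 and 15.8 expected for independent calls, and went opposite ways in 11 and 16 genes. With fry for members that move together, 5, 4, 0 and 8 lists passed in mPFC (susceptible-control, resilient-control, susceptible-resilient, pooled), 0 in each amygdala contrast, 2, 7 and 0 for the tissue differences and 12 for controls between tissues. For members in either direction these were 26, 17, 0 and 25 in mPFC, 5, 23, 2 and 19 in amygdala, 25, 22 and 0, and 31.

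The real split was compared with others of the same sizes, which leave litter or GC trends along the groups open. With phenotypes pooled, only the real split of 84 gave as many genes in mPFC (2281, highest other 0) and amygdala (217, highest other 13). Chance splits are an unlikely source of both. In mPFC only the real split of 84 reached the correlation of the 2 phenotypes' fold changes (0.893, highest other 0.836). In amygdala 15 of 84 reached its 0.612 (highest other 0.894), so chance stays open. Shared controls can raise either value. For the tissue difference of susceptible against resilient offspring (0 genes) 100 of 100 splits were as large, the highest other giving 1. In the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. There the real and highest other counts were 1705 and 0, 122 and 0, and 0 and 0 genes in mPFC (1, 1 and 10 splits as large), in the order susceptible-control, resilient-control and susceptible-resilient. In amygdala they were 0 and 0, 355 and 4, and 0 and 0 (10, 1 and 10 splits). For controls between tissues they were 2778 and 803 (1 split). For lists they were 9 and 14, 9 and 13, and 4 and 7 in mPFC (4, 7 and 7 splits), and 11 and 9, 7 and 14, and 9 and 14 in amygdala (1, 7 and 8 splits).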
